A study of Homo sapiens with 4 samples.

How the data were processed

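RNA from the human T cell acute lymphoblastic leukaemia line ALL-SIL was measured on Affymetrix U133 Plus 2 arrays, on which each transcript is read by a set of short 3′-biased probes (a probe set). Per the labels' protocols, the cells were infected with lentivirus made in HEK293T cells from supernatant collected at 48 h. The virus carried the pLKO.1 vector with either a short hairpin RNA against TLX1 or a luciferase control. Cells were then selected in puromycin for 5 days and passed over Ficoll before total RNA was taken. There were 4 arrays, 2 per group, described as duplicate experiments. Nothing states whether the duplicates came from separate infections, so the p-values measure only the spread between these arrays, which may be partly technical.

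The deposited table gave 1 linear intensity for each of 54675 probe sets and 4 arrays, and all 4 columns were used. The summary method, background correction and scaling used by the authors to make these intensities are not given in the sources used here. The values were taken as already scaled, because the array medians after log2 transformation lay within 0.5 of each other, the limit set beforehand. They ran from 5.91 to 6.25. No detection calls came with the intensities, so a dim probe set could not be called absent, and 2.46% to 7.92% of probe sets per array were listed at 0. The number of arrays, 2 per group, limits the precision.

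Intensities were transformed as log2(value + 16). Differences are therefore on that scale, which understates the change of dim genes. Probe sets were named from the platform annotation. Of the probe sets, 41097 carried 1 gene symbol, 1801 carried several and 11777 were not listed. The last 2 kinds, and 62 control probe sets, were left out of the gene tests. Symbols were updated through Entrez identifiers with the RefSeq table of assembly GRCh38 for 41043 probe sets and kept as annotated for 54. Each gene was represented by its probe set with the highest mean over all 4 arrays, which gave 19775 genes. No genome was used, so no coordinates are given.

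Differences between shTLX1 and control were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) without a replicate term, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit had 2 residual degrees of freedom and borrowed 4.56 from the spread of other genes. On simulated arrays with the same 19775 genes and spreads, 200 genes were changed. The fit called 19.4% of 67 genes changed by a log2 of 1, 85.1% of 67 changed by 2 and 100% of 66 changed by 4, together with 16 unchanged genes. Simulated genes were independent, with the same spread in both groups. On the real arrays the SD of the log2 difference was 0.837 between the controls and 0.397 between the shTLX1 arrays. The simulated rates therefore do not carry over to them.

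Fixed lists totalling 706 entries (675 distinct genes, 598 measured) were tested with limma's camera at a preset between-gene correlation of 0.01, adjusted over 26 lists. The lists covered leukaemia transcription factors, T cell receptor signalling, thymocyte stages, NOTCH1 and MYC targets, cell cycle, apoptosis, p53, interferon, stress, metabolism, ribosomes, histones and, as other cell types, B, myeloid, NK, erythroid and HEK293T or epithelial markers. Camera compares a list with all other genes, so its direction is relative to them. Camera with an estimated correlation and fry were run beside it, fry asking only whether a list's genes move, on balance, one way. With an estimated correlation, camera also tests on the 2 residual degrees of freedom only, so few lists can pass. In simulated arrays with independent genes, camera found a 30-gene list shifted by a log2 of 0.5 and gave an unadjusted p under 0.05 for 6 of 200 unshifted lists. That rate does not carry over to lists whose genes move together, and the estimated correlation reached 0.422 among the called lists.

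The lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule took TLX1, then 12 higher and 12 lower genes by size among those past the threshold, with a mean at or above the median gene and no overlap between groups. Places not filled went to the genes with the smallest unadjusted p under the same 2 conditions. It added up to 4 members per list and 11 genes of interest, among them RUNX1, for which no probe set carried that gene alone. Not every gene so chosen is described below. Uncharacterised symbols were passed over. Alternatives were a replicate block, quantile normalization, median centring, the mean of a gene's probe sets, testing all probe sets, a filter on dim genes, other variance models, pseudocounts of 1 and 64, and leaving out each array in turn.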

Results

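The comparison asked how the transcriptome of ALL-SIL, a T cell acute lymphoblastic leukaemia line with a rearranged TLX1 locus, differs when TLX1 is targeted by a short hairpin RNA. TLX1 is a homeobox transcription factor that is not normally made in thymocytes. Intensities came from 2 arrays of luciferase control cells (control 1 and 2) and 2 arrays of cells carrying the TLX1 hairpin (shTLX1 1 and 2). Median probe set intensities were 53.1 and 44.0 in the controls and 56.0 and 60.1 in the shTLX1 arrays.

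The control arrays differed from each other more than the shTLX1 arrays did. Across 19775 genes, 4617 lay at least 2-fold apart between control 1 and control 2, against 469 between the shTLX1 arrays, and the correlations were r = 0.913 and r = 0.980. The controls were also less alike than any pair of a control and a shTLX1 array, for which r ran from 0.939 to 0.952. Control 2 lay further from the shTLX1 arrays (3046 and 3323 genes at least 2-fold apart) than control 1 did (1623 and 1950). Genes are not independent replicates, so these correlations describe the arrays only. Control 1 stood apart in the control probe sets that measure RNA quality. Its 3′/5′ ratio was 3.83 for GAPDH and 6.96 for ACTB, while the other 3 arrays lay between 0.911 and 0.940 for GAPDH and between 1.20 and 1.32 for ACTB. The 18S ribosomal RNA probe set for the middle of the transcript read 876 in control 1 and 11.2 to 49.8 in the others. Control 2 had 4331 probe sets listed at 0, against 1343 to 1688 on the other arrays.

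**Figure D1:**
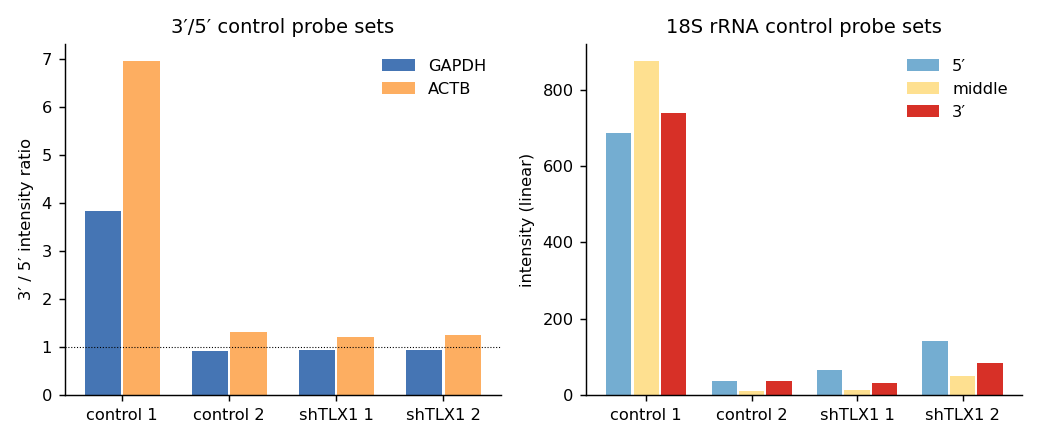
Left, ratio of 3′ to 5′ intensity of the GAPDH and ACTB control probe sets on each of the 4 arrays, with a dotted line at a ratio of 1, and right, linear intensity of the 5′, middle and 3′ probe sets of 18S ribosomal RNA. Control 1 stands apart in both panels, with ratios of 3.83 and 6.96 and a middle 18S intensity of 876.

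TLX1 itself was lower in both shTLX1 arrays than in either control. Its only probe set read 684 and 664 in the controls and 500 and 411 in the shTLX1 arrays. The means were 674 ± 14.1 and 456 ± 62.8 (SD, n = 2 each), so the mean signal with the hairpin was 67.6% of control. The log2 difference was -0.55 (standard error 0.25, 95% confidence interval -1.17 to 0.06). This did not pass the threshold in limma, with an adjusted p of 0.954, and 6.95% of all genes had a smaller p. An exact two-sided permutation test cannot go below p = 0.333 with 2 arrays against 2, and gave that value.

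No single gene passed the threshold between shTLX1 and control cells. Limma called 0 of 19775 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.954. At an unadjusted p under 0.05 there were 973 genes, 702 higher and 271 lower in shTLX1, where chance alone gives 989. At an unadjusted p under 0.01 there were 158 genes, where chance gives 198. The groups did not overlap for 35.2% of genes, where chance gives 33.3%. The median gene was 0.09 higher on the log2 scale in shTLX1. After quantile normalization it was -0.09, and 407 genes were then higher and 685 lower at an unadjusted p under 0.05. After median centring it was -0.11, with 335 higher and 741 lower, so the sign of small differences depends on the scaling. Without control 1, 5764 genes had an unadjusted p under 0.05, and without control 2 there were 4042, with 0 past the adjusted threshold each time. Without shTLX1 1 there were 190 and without shTLX1 2 there were 132.

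Among the genes that headed the ranking, CXCR6, FXYD2 and LIG4 were higher in both shTLX1 arrays than in either control, as the selection required. None of the genes named here passed the adjusted threshold. CXCR6, a chemokine receptor of activated and memory T cells, had a log2 level of 5.28 ± 1.02 in control and 8.69 ± 0.69 in shTLX1 (SD, n = 2 each). That is 10.7-fold on the log2(value + 16) scale, and its other probe set was higher by 3.14. The log2 difference of CXCR6 was 4.13 against control 1 and 2.69 against control 2. FXYD2, a regulatory subunit of the sodium-potassium ATPase, went from 8.51 ± 0.15 in control to 10.15 ± 0.22 in shTLX1, a 3.13-fold difference. ATP2B4, a plasma membrane calcium pump, was 2.69-fold higher. LIG4, the ligase of non-homologous end joining that also closes V(D)J junctions, was 2.63-fold higher, and its other probe set was higher by 2.80 on the log2 scale. RAB21, a small GTPase of endosomal traffic, was 2.86-fold higher, while 2 of its 3 other probe sets differed by 0.12 and 0.04 on the log2 scale. The serine protease TMPRSS3 was 5.24-fold and the telomere maintenance gene CTC1 3.67-fold higher. The 2 other probe sets of TMPRSS3 differed by 0.25 and 0.44, and 1 of 2 for CTC1 had the same sign. The non-coding RNA LINC01425 was 3.76-fold and TMEM202-AS1 2.16-fold higher.

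Some leading probe sets were not matched by the others of their gene. For ID4, an inhibitor of basic helix-loop-helix factors, the brightest probe set was 7.66-fold higher, while its 4 other probe sets differed by 0.10 to 0.48 on the log2 scale. For THBS1, a secreted matrix glycoprotein, it was 2.01-fold higher and only 1 of 6 other probe sets had the same sign, the mean of all being -0.027. For PAPPA, a secreted metalloproteinase, it was 2.22-fold higher and 6 of 10 others had the same sign.

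At the other end of the ranking, BCAT1, PCK2 and ABCC8 were among the genes lower in both shTLX1 arrays than in either control. The selection required this separation too, and none passed the adjusted threshold. BCAT1, which transaminates branched-chain amino acids, had a log2 level of 10.60 ± 0.49 in control and 8.87 ± 0.01 in shTLX1 (SD, n = 2 each), 3.32-fold lower, and its 3 other probe sets differed by -1.70 to -0.29. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 3.35-fold lower. ATF5, a stress-induced transcription factor, was 2.81-fold lower, and the tryptophanyl-tRNA synthetase WARS1 2.72-fold lower. The other probe set of WARS1 had a log2 level of 7.98 in control 1, below both shTLX1 arrays at 8.91 and 8.87, and 11.03 in control 2. ABCC8, the sulphonylurea receptor, was 4.70-fold lower, although its other probe set differed by 0.10 in the opposite direction. JDP2, a repressor of AP-1, was 3.03-fold lower, and its other probe set was higher by 0.76. ACTN1, an actin cross-linker, was 2.58-fold lower. RAB3GAP1, MAGEF1, CREG1 and TOP1MT were 2.65-fold, 2.84-fold, 2.60-fold and 2.52-fold lower. The 3 other probe sets of ACTN1 differed by -0.51 to -0.17 and those of RAB3GAP1 by -0.70 to -0.19. METTL9 was 1.97-fold lower, with 1 of 3 other probe sets of the same sign.

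**Figure D2:**
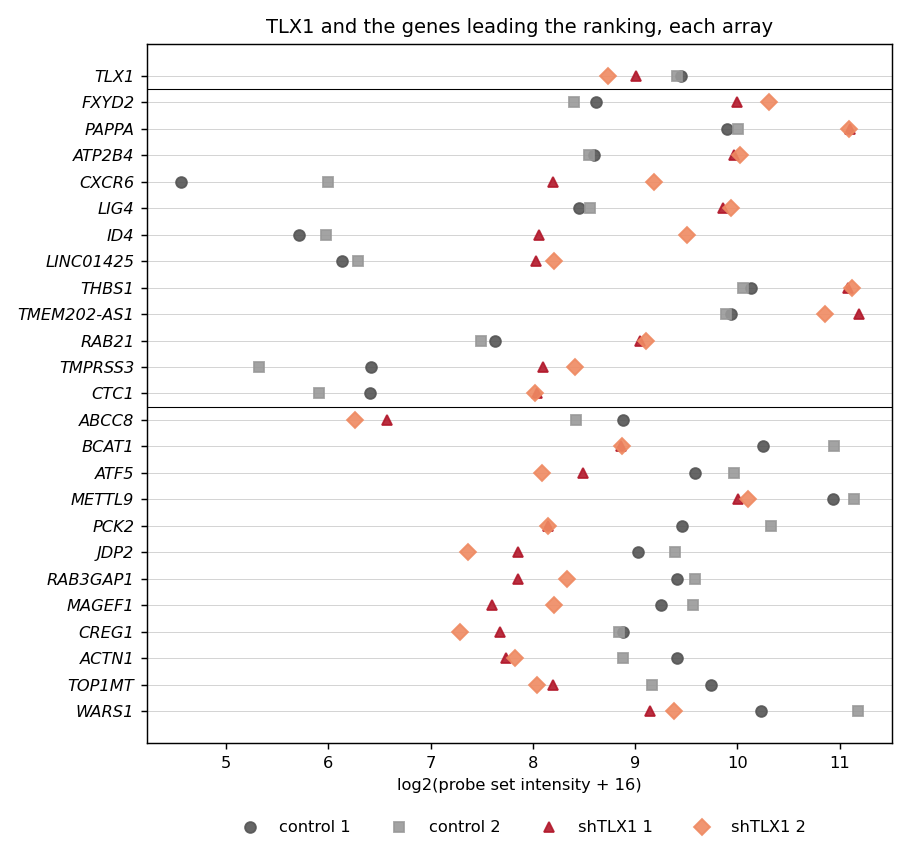
Log2(intensity + 16) of TLX1, of the 12 leading higher genes and of the 12 leading lower genes on each of the 4 arrays, with grey symbols for controls and red or orange symbols for shTLX1 arrays. The groups did not overlap for TLX1 or for the leading genes, for which the rule of selection required it, and none passed the adjusted threshold of 0.05.

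The fixed gene lists were then compared with all other genes. Camera called 10 of 26 lists, 7 higher and 3 lower in shTLX1. With an estimated correlation it called 0, and each of the 10 then had adjusted p = 0.655. That setting also leaves only 2 degrees of freedom, so it cannot tell whether correlation between genes made the calls. For the T cell receptor list the estimated correlation was 0.0075, below the preset 0.01. Its unadjusted camera p still went from 5.31e-05 to 0.0534. With fry, which also rests on the 2 residual degrees of freedom, 0 of 26 lists passed, the smallest adjusted p being 0.150. When the 4 arrays were split in the 2 other possible ways, each side holding 1 control and 1 shTLX1 array, camera called 6 and 4 lists. Without control 1, 6 of the 10 calls held, without control 2, 4 held, and 2 held in both cases, those of the cholesterol synthesis and mitosis lists. Over all alternatives, the highest adjusted p of the called lists was 0.655, except 0.955 for replication and 0.742 for unfolded protein and amino acid stress.

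Cholesterol synthesis genes gave the largest list median against the mean of both controls. Against control 1 alone the median of the NK and cytotoxic T cell list was larger, at 0.64. Of 18 measured, 17 were higher in shTLX1, with a median of 0.77 on the log2 scale (1.70-fold). Over all genes tested, 0 members passed, and 7 rose when adjusted over the list alone. These were MVD, STARD4, HMGCS1, INSIG1, IDI1, SQLE and LSS. HMGCS1, which makes HMG-CoA for the mevalonate pathway, was at 9.42 ± 0.45 in control and 10.74 ± 0.15 in shTLX1 (SD, n = 2 each), 2.51-fold higher. STARD4, a sterol carrier, was 2.93-fold higher, and INSIG1, a sterol-responsive regulator of SREBP processing, 2.03-fold higher. MVD read 4.32 and 0 in the controls and 55.5 and 75.5 in the shTLX1 arrays. Camera gave the list an adjusted p of 3.72e-08, and adjusted p = 0.655 with an estimated correlation. The median was 0.47 against control 1, the array with raised 3′/5′ ratios, and 1.01 against control 2.

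The mitosis list was called higher in shTLX1 and the replication list lower. Of 34 mitosis genes, 32 were higher, with a median of 0.39 (1.31-fold), and the groups did not overlap for 20 of them, where chance gives 33.3% of genes for both directions together. None passed over all genes tested or when adjusted over the list alone (0 of 34 each). The motor KIF11 was at 9.31 ± 0.33 in control and 10.26 ± 0.21 in shTLX1 (SD, n = 2 each). TOP2A, the mitotic topoisomerase, was 1.80-fold higher, UBE2C, of the anaphase-promoting machinery, 1.54-fold higher and KIF23 3.26-fold higher. For the mitosis list the camera adjusted p was 1.93e-07, and adjusted p = 0.655 with an estimated correlation. The median was 0.22 against control 1 and 0.60 against control 2.

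Of 31 replication and G1/S genes, 20 were lower, with a median of -0.15 and 0 members past the threshold over all genes or adjusted over the list alone. CCNE1, the G1/S cyclin, went from 8.18 ± 0.11 in control to 7.13 ± 0.06 in shTLX1 (SD, n = 2 each), and MCM3, of the replicative helicase, had a log2 difference of -0.49. CHEK1, the replication checkpoint kinase, differed by -0.042 and was higher by 0.26 when control 2 was left out. The camera adjusted p was 9.26e-04, and adjusted p = 0.655 with an estimated correlation. The median was -0.07 against control 1 and -0.29 against control 2. Without control 2 the adjusted p was 0.955, and with the mean of each gene's probe sets 0.0723.

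The list of T cell receptor genes was called higher in shTLX1, while the thymocyte stage lists were not called. Of 27 measured genes of the T cell receptor complex and its signalling, 23 were higher and the groups did not overlap for 14. The median was 0.36 (1.28-fold), and 0 members passed over all genes or adjusted over the list alone. The kinase LCK was at 11.15 ± 0.20 in control and 11.70 ± 0.06 in shTLX1 (SD, n = 2 each), 1.47-fold higher. The zeta chain CD247 was 1.42-fold, the thymocyte selection gene THEMIS 1.66-fold and the adaptor LCP2 1.92-fold higher, although the other probe set of CD247 differed by -0.35. Camera's adjusted p for these genes was 4.60e-04, and adjusted p = 0.655 with an estimated correlation. Without control 1, the array with raised 3′/5′ ratios, it was 0.0996. The list median was then 0.40, where the median of all genes was 0.21.

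Of 20 measured genes in the list of this leukaemia's tumour suppressors, transcription factors and chromatin regulators, 18 were higher. The list had a median of 0.33 and 0 members past either adjustment. BCL11B, a factor of T cell commitment, was at 10.20 ± 0.37 in control and 10.92 ± 0.26 in shTLX1 (SD, n = 2 each), 1.65-fold higher. Its 2 other probe sets were higher by 0.31 and 1.42. At the first of these, control 1 and shTLX1 1 both read 10.56, so the groups overlapped. GATA3 was 1.51-fold higher, and its 2 other probe sets were higher by 0.52 and 0.67. The camera adjusted p was 8.94e-03, adjusted p = 0.655 with an estimated correlation, 0.208 without control 1, 0.0846 without control 2 and 0.202 without shTLX1 2.

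The heat shock, histone and ribosomal protein lists were also called, at the preset correlation. Heat shock genes had a median of 0.30, with 13 of 17 higher, among them the co-chaperones DNAJB1 (1.77-fold) and STIP1 (1.70-fold). The median was 0.02 against control 1 and 0.55 against control 2. Their camera adjusted p was 6.84e-03, adjusted p = 0.655 with an estimated correlation and 0.499 without control 2. Histone genes had a median of 0.45, with 18 of 20 higher, and H2BC6 was 2.19-fold higher. Their median was 0.31 against control 1 and 0.52 against control 2. Their adjusted p was 0.0273, adjusted p = 0.655 with an estimated correlation, 0.350 without control 1, 0.107 without control 2, 0.416 without shTLX1 2 and 0.0723 with the mean of probe sets. Ribosomal protein genes had a median of -0.05, with 24 of 32 lower, and medians of -0.03 and -0.06 against control 1 and 2. Their adjusted p was 0.0248, adjusted p = 0.655 with an estimated correlation, 0.619 without control 2, 0.377 without shTLX1 2, 0.284 after quantile normalization, 0.158 with the mean of probe sets and 0.195 without an intensity trend. In these 3 lists 0 members passed either adjustment.

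The list of unfolded protein and amino acid stress genes had a median of -0.26, with 17 of 29 lower and 0 members past either adjustment. SESN2, a leucine sensor, went from 9.37 ± 0.72 in control to 8.13 ± 0.12 in shTLX1 (SD, n = 2 each), and SHMT2, of serine metabolism, had a log2 difference of -0.67. The chaperones PDIA4 and HSP90B1 of the endoplasmic reticulum were 1.57-fold and 2.29-fold higher, although the other probe set of PDIA4 differed by -0.12. For HSP90B1 the log2 difference was 1.92 against control 1 and 0.47 against control 2. The camera adjusted p was 0.0273, and adjusted p = 0.655 with an estimated correlation. The list median was -0.01 against control 1 and -0.49 against control 2. Without control 2 the direction turned upwards, with an adjusted p of 0.404. The adjusted p was 0.134 after quantile normalization, 0.0939 after median centring, 0.0511 without an intensity trend and 0.0865 without shTLX1 2.

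Lists of thymocyte stage and NOTCH1 targets did not pass. Of 32 genes of cortical and maturing thymocytes, 20 were higher and 12 lower, with a median of 0.14 (camera adjusted p = 0.622). Single members differed by much but so did the controls. ID2, an inhibitor of E proteins, was at 7.42 ± 2.42 in control and 10.94 ± 0.83 in shTLX1 (SD, n = 2 each). S1PR1, the receptor for thymic exit, was at 5.20 ± 1.13 and 7.98 ± 1.02, its regulator KLF2 at 8.35 ± 1.70 and 10.27 ± 0.85, and the chemokine receptor CCR7 at 7.72 ± 1.62 and 5.50 ± 0.42. Log2 differences were 0.34 for PTCRA, -0.30 for RAG1 and 0.27 for RAG2, with standard errors of 0.40, 0.45 and 0.38. The other probe sets of PTCRA differed by -0.80 and 0.83. RAG1, a dim gene like RAG2, became 0.16 without control 2 and 0.085 with the mean of its probe sets. RAG2 became -0.020 without shTLX1 2 and -0.0016 after quantile normalization.

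Of 24 NOTCH1 targets, 12 were higher and 12 lower, with a median of 0.02 (camera adjusted p = 0.850). TRIB2 was 2.45-fold, IL7R, the interleukin 7 receptor, 3.62-fold and CD300A 4.90-fold higher. Their log2 differences against control 1 and control 2 were 1.71 and 0.87 for TRIB2, 1.22 and 2.49 for IL7R and 3.04 and 1.54 for CD300A. HES1, the canonical NOTCH effector, had a log2 difference of -0.81. For CD300A and HES1, 1 of 2 other probe sets had the same sign. NOTCH1 differed by 0.20 with a standard error of 0.20, and by -0.15 with the mean of its probe sets and -0.0025 after median centring. MYC was 1.36-fold higher, at 10.97 ± 0.33 in control and 11.41 ± 0.20 in shTLX1 (SD, n = 2 each). The early thymocyte list had a median of 0.10 (camera adjusted p = 0.850), and the list of TLX1 and other leukaemia transcription factor oncogenes 0.15 (camera adjusted p = 0.850).

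The lists of apoptosis, p53, interferon, NF-kappaB, immediate early, metabolic and MYC target genes did not pass either. The BCL2 family and apoptosis list had a median of 0.11 (camera adjusted p = 0.712), and BCL2 differed by 0.06, with -0.43 when control 1 was left out, -0.13 without shTLX1 2, -0.051 after quantile normalization and -0.15 after median centring. The p53 target list had a median of 0.07 (camera adjusted p = 0.561), and CDKN1A, the cell cycle inhibitor, differed by -0.62 with a standard error of 0.37. In that list 13 genes were higher and 12 lower. DDB2 differed by -1.02 and GADD45A by 1.06, neither past the adjusted threshold. Interferon-stimulated genes had a median of 0.15 (camera adjusted p = 0.507). The medians were 0.12 for NF-kappaB targets (camera adjusted p = 0.850), 0.21 for immediate early genes (0.625), 0.05 for glycolysis and hypoxia (0.822), 0.02 for oxidative phosphorylation (0.712) and -0.01 for MYC targets and ribosome biogenesis (0.712). For the p53, glycolysis and oxidative phosphorylation lists camera's direction, which is relative to all other genes, was downwards although the median was above 0. The mean of the p53 list was -0.0032. That of the MYC target list was 0.058, where the median was below 0 and camera's direction was downwards. Without control 1 the MYC target list passed upwards (adjusted p = 0.0320), and without control 2 it passed downwards (adjusted p = 1.07e-03). Glycolysis genes passed downwards without control 1 (adjusted p = 0.0320), and oxidative phosphorylation genes passed after median centring (adjusted p = 0.0413).

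Markers of other cell types were mostly dim. The list of NK and cytotoxic T cell genes was higher, with 12 of 16 members up, a median of 0.73 and 0 members past either adjustment. Its camera adjusted p was 0.0249, adjusted p = 0.655 with an estimated correlation, 0.456 without control 1 and 0.522 among the brighter genes only. IL2RB, a receptor chain that T cells also make, read 356 and 1001 in the controls and 1165 and 1598 in the shTLX1 arrays, while GZMB read at most 40.7 on any array. B cell markers had a median of 0.10 (camera adjusted p = 0.783) and myeloid markers -0.13 (0.144). Erythroid and megakaryocyte markers had a median of -0.19 (0.231), and markers of HEK293T and epithelial cells, the source of the virus, -0.16 (0.263). Without control 1 the myeloid, erythroid and HEK293T lists passed downwards, with adjusted p values of 0.0324, 0.0368 and 0.0361.

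**Figure D3:**
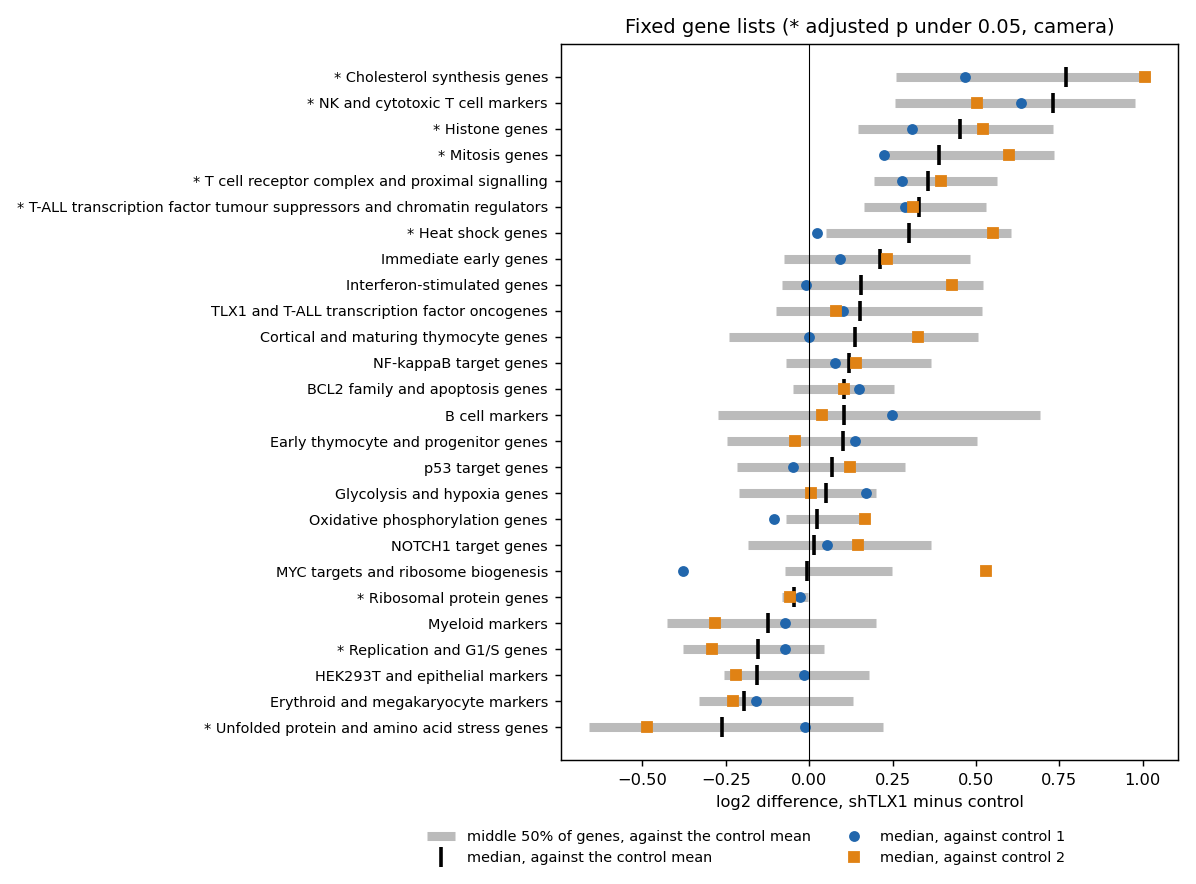
Log2 difference of each fixed gene list between shTLX1 and control, with the middle 50% of genes as grey bars the median as a black tick, and blue circles and orange squares for the median against control 1 and control 2. Asterisks mark the 10 lists with a camera adjusted p under 0.05, and the cholesterol synthesis list lies at 0.47 and 1.01 against the controls, while the MYC target and ribosome biogenesis list lies at -0.38 and 0.53.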

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

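All alternatives here were planned. The number of genes past the adjusted threshold was 0 under 14 of 15 alternatives. The exception was the replicate block, which called 104 genes, 86 higher and 18 lower, 95 of them at least 2-fold. That fit has 1 residual degree of freedom and in effect used 1 spread for genes of like intensity. Its total was about 19780 degrees of freedom, a rounded value. The main fit was set beforehand without a replicate term. Deviations of same-numbered arrays correlated at r = 0.0569 across genes, but 2 pairs cannot show whether the numbers pair the arrays. Among the calls with the replicate block were FXYD2, CXCR6, BCAT1 and ID2, and it also called the cortical and maturing thymocyte list (adjusted p = 0.0211). The number of genes at an unadjusted p under 0.05 was 3797 with all 54613 probe sets tested and 528 among the 9888 brighter genes, that is 6.95% and 5.34% of those tested against 4.92%, for a cause that was not tested. It ran from 132 without shTLX1 2 to 5764 without control 1, in fits where the lone array of a group is assumed to vary like the other group. No background values came with the arrays, so what dim genes could show is not known. After median centring, 335 of these genes were higher and 741 lower, and with quantile normalization 407 and 685, against 702 and 271 in the values as deposited. TLX1 was lower under all 15 alternatives, between -0.76 and -0.42, with adjusted p from 0.202 to 1. The number of lists called ran from 5 without control 2 to 11 without control 1, was 6 without shTLX1 2, and was 0 with an estimated correlation and with fry. Under the other alternatives run for lists it was 7 to 11. Lists were not tested with robust eBayes, the ordinary t statistic or all probe sets.

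Among named genes, directions turned for THBS1 (-0.027), NOTCH1 (-0.15) and RAG1 (0.085) with the mean of a gene's probe sets, for RAG2 (-0.0016) and BCL2 (-0.051) with quantile normalization, and for NOTCH1 (-0.0025) and BCL2 (-0.15) with median centring. With each array left out, RAG1 ran from -0.77 to 0.16, RAG2 from -0.020 to 0.56, CHEK1 from -0.34 to 0.26 and BCL2 from -0.43 to 0.54. Camera's direction turned for lists that had not passed and, without control 2, for the unfolded protein and amino acid stress list, which had. Adjusted p values after the turn were 0.976 (replicate block) and 0.376 (brighter genes) for leukaemia oncogenes, 0.989 and 0.752 for NF-kappaB targets and B cell markers (mean of probe sets), and 0.997 for NOTCH1 targets (no trend). Fry's direction was opposite to camera's for MYC targets (fry adjusted p = 0.960) and for glycolysis and oxidative phosphorylation (0.939 each). The means of these 3 lists were above 0 (0.058, 0.021 and 0.023), while the median of all genes was 0.09. Fry does not compare a list with other genes and camera does, so the tests can differ on the same values. With each array left out, the adjusted p of lists whose direction turned ran from 0.445 to 0.962 for leukaemia oncogenes, 0.320 to 0.913 for early thymocyte genes, 0.352 to 0.951 for NOTCH1 targets, 0.00107 to 0.824 for MYC targets, 0.107 to 0.933 for apoptosis, 1.90e-05 to 0.404 for amino acid stress, 0.619 to 0.882 for NF-kappaB, 0.320 to 0.823 for immediate early genes, 0.0320 to 0.913 for glycolysis, 0.141 to 0.913 for oxidative phosphorylation, 0.518 to 0.894 for B cell and 0.0361 to 0.856 for HEK293T markers. The MYC target list passed in opposite directions without control 1 (0.0320, higher) and without control 2 (0.00107, lower). The cause of the turns in camera's direction was not tested.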

Other observations

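The tests of the array splits, of the stress gene groups and of single controls as a cause were chosen after the results had been seen, while the test of the tRNA synthetases was chosen before its result, though its reading was revised after. The control arrays also differed in gene groups, and with 1 array against 1 no test separated biology from RNA quality or scaling. Genes of ribosome biogenesis and MYC targets were lower in control 2 than in control 1 with a median difference of -0.98 on the log2 scale. The shTLX1 arrays lay between them, with medians of -0.38 against control 1 and 0.53 against control 2. Of the 18 amino acid response genes in the stress list, split off after the data were seen, 15 were higher and 3 lower in control 2 than in control 1, with a median of 1.02. Among genes picked after their values were seen, DDIT3, the stress factor CHOP, was at 8.32 in control 1, 9.77 in control 2 and 8.20 and 7.96 in the shTLX1 arrays. TRIB3, a pseudokinase induced with it, was at 9.16, 11.36, 9.89 and 9.81. Asparagine synthetase, ASNS, went the other way, at 8.54, 6.78, 8.63 and 8.32, and PSAT1 and VLDLR were the others lower in control 2. The 11 endoplasmic reticulum genes of the same list differed between the controls by a median of -0.06, but in both directions. In control 2, 5 were higher and 6 lower than in control 1. HSP90B1 was at 7.24 in control 1 and 8.69 in control 2, and CALR at 11.32 and 10.28. Of the 11, 8 were higher and 3 lower in shTLX1, among the latter HERPUD1 (-0.66) and SDF2L1 (-0.41).

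The lower level of the unfolded protein and amino acid stress list in shTLX1 may rest on control 2, since without that array the list's direction turned, with a camera adjusted p of 0.404. A lower amino acid response of the kind driven by ATF4 in the shTLX1 cells was tested on tRNA synthetases. Those that ATF4 induces should then lie below the others against each control. The permutation shuffled genes between the classes, so its p-values carry no replication over arrays. The 11 responsive genes differed from the 6 others by -0.30 against the mean of both controls (two-sided permutation p = 0.0791), by -0.80 against control 2 (permutation p = 0.0437) and by 0.30 against control 1 (permutation p = 0.0433). Without WARS1 and GARS1, whose values had been seen before, these were -0.19 (permutation p = 0.113), -0.77 (permutation p = 0.0319) and 0.31 (permutation p = 0.00307). A value above 0 had been set beforehand as excluding the response, but the other synthetases, taken as level, differed by -0.63 between the controls and had a median of -0.48 against control 1, where the responsive genes had -0.18 with 8 of 11 lower, so the test decides neither way.

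The higher cholesterol synthesis and mitosis lists were weighed against the state of each control array. If shortened RNA in control 1 were the whole cause, the differences should go when that array is left out. The camera adjusted p was then 2.51e-04 for cholesterol synthesis and 6.65e-05 for mitosis, with the direction kept. Without control 2 it was 3.02e-03 and 0.0110. The list medians were 1.01 and 0.60 against control 2, where that of all genes was 0.21. They were 0.47 and 0.22 against control 1, where that of all genes was -0.05. Both lists thus lay above other genes against either control. A fit with 1 control left cannot exclude a cause in the arrays, since the MYC target list passed in opposite directions in such fits. With an estimated correlation, on 2 degrees of freedom, neither list passed. A single hairpin cannot separate loss of TLX1 from other effects of that hairpin, which was not tested.

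Whether the higher T cell receptor list rests on the RNA quality of control 1 stays open. Without control 1 its camera adjusted p was 0.0996 with the direction upwards. The list median went from 0.36 (quartiles 0.20 to 0.56) to 0.40 (quartiles 0.23 to 0.57), but that of all genes went from 0.09 to 0.21, so the list stood out less from the other genes, and only 1 control was left. Without control 2 the adjusted p was 2.37e-03 with the direction upwards. Against control 1 alone the list median was 0.28, where that of all genes was -0.05. Only control 1, the array with raised 3′/5′ ratios, was left in that fit, so it cannot exclude a cause in either control. With an estimated correlation over all arrays the adjusted p was 0.655, but on 2 degrees of freedom few lists can pass. A response to TLX1 knockdown may also raise these genes, and it was not separated from the hairpin's other effects.

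In the 2 splits that each mix 1 control and 1 shTLX1 array per side, limma gave 667 and 521 genes at an unadjusted p under 0.05, against 973 in the real split. The smallest list adjusted p in these splits was 7.20e-04 and 2.40e-06, against 3.72e-08. The cholesterol synthesis list had adjusted p values of 0.981 and 0.116 in them, and the mitosis list 0.441 and 0.146. The 3 splits in all are too few for a share under 0.05. Of 200 random lists of 30 genes on the real arrays, 5 had a camera p under 0.05. Randomly drawn genes need not move together as listed genes can, so that rate does not carry over to the fixed lists.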
